A study of Mus musculus with 8 samples.

How the data were processed

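The data are RNA-seq libraries of mouse cells, 2 for each of 4 groups: FAP+ cells sorted from visceral adipose tissue, skeletal muscle and pancreas, and FAP-negative MEFs grown for 3 passages. Per the labels, RNA was prepared with a Purelink kit, amplified with MessageAmp, which copies RNA from its poly(A) tail, and made into libraries with the Illumina mRNA kit. Amplification from the tail favours sequence near the 3' end, so levels of different genes within a library are compared with care. The authors deposited 3 tables for the series. Per the file headers, 1 table holds estimated counts of fragments after a bias adjustment, with values that need not be whole, another the matching bias-adjusted FPKM values, and another RPKM values, all deposited per gene and library. The submitters' processing notes name Bowtie2, TopHat2, HTSeq, edgeR and the mouse build mm9, with no versions, roles or order. The program behind the bias adjustment is not given in the sources used here. No coordinates are printed, since the reference at hand is of another build, and it served only for gene symbols and for which genes lie on chromosomes X and Y. The fragment and FPKM tables list 22558 genes and the table of RPKM lists 22609. Of the identifiers, 20438 matched a current symbol, 1947 an older one and 224 neither. Of the columns in each table, 8 were matched to the samples by name, and 6 others were not used here. Published T-cell data that the design text mentions were not used here.

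Estimated fragments totalled 25455781 and 27759399 in adipose, 15516319 and 22813325 in muscle, 17593056 and 17102944 in pancreas and 25433575 and 25155326 in MEFs. One floor was used throughout, 3 fragments per library, equal to 0.108 to 0.193 CPM before scaling. Intervals and floors cover counting error only, since amplified fragments are not independent molecules. The RPKM values of a gene were whole multiples of 1 step per library, which gave whole reads for 21784 genes, with 100% of values whole within a tolerance of 0.01 and 825 genes without a usable step. These reads totalled 9509792 to 16830845 per library.

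The design had been fixed for counts. As the table held estimated counts, these were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM factors, filterByExpr on the 4 groups and no covariates. All 8 libraries entered 1 fit, which left 4 residual degrees of freedom and a common biological coefficient of variation of 33.2%. The TMM factors were 0.516 and 0.889 in adipose, 1.01 and 1.02 in muscle, 1.09 and 1.13 in pancreas and 1.31 and 1.31 in MEFs. The filter left 14847 genes, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within each of 6 comparisons. Calls depend on the size of a change and on these spreads. Genes were called shared if they passed in the same direction against MEFs in all 3 tissues, and distinct if they were higher in a tissue than in both other FAP+ populations. A group with 0 fragments gives a fold only as a lower bound at the floor, and 1 to 3 fragments give a ratio with its 95% counting interval.

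Gene lists, 35 in all, were fixed before the data were examined, 21 for the stromal cells and 14 for other cell types that a sort or culture could hold. Of these 34 had enough measured members to test, by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was also run with an estimated correlation. Some genes stand in more than 1 list or are also expressed by stromal cells, among them Spp1, Krt8, Wt1, Acta2, Tagln, Des, Il6 and Egr2. The genes named were chosen by a rule, also fixed before the data were examined. Per comparison it took Fap and Dpp4, then the 6 highest and 6 lowest genes by the ratio of mean CPM + 1 among called genes with at least 10 CPM in both libraries of the higher group. It added up to 4 called members of each list that passed, and Fst, Lama2, Igf1, Kitl, Cxcl12 and Il6 everywhere. For the shared and distinct results it took 6 genes by the smallest ratio, and for other cell types the 2 members with the highest CPM. Predicted genes were left unnamed. Some genes the rule took are not reported here, though counts over the named genes include them.

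Shared calls were set beside 20 simulations in which all 8 libraries, MEFs included, were drawn with 1 mean per gene over all groups. No gene differs in them, so counts near 0 follow by construction and give no chance level for overlap. Similarity of libraries was tested by exact permutation, one-sided. The alternatives fixed beforehand were RLE and upper quartile scaling, DESeq2 (1.42.0), no filter, a filter of 5 CPM in 2 libraries, a fit of only the groups compared, the replicate number as a block, a test against a 2-fold change, and each library left out in turn. They also included limma with a trend on log2(FPKM + 1), on log2(FPKM + 0.1), and on genes at 1 FPKM or more in 2 libraries. A fold on the scale of log2(FPKM + 1) understates the change of low genes. The FPKM fits used no TMM or other added scaling between libraries. Their medians over all genes and shares of higher genes can therefore carry offsets between libraries. Others were added after seeing the data: edgeR on the recovered reads, the same without adipose library 1, and list medians under each scaling. On recovered reads 14354 genes passed the filter and edgeR called 8124, 8002 and 7689 genes against MEFs in adipose, muscle and pancreas. Their folds moved by over 1.5 times for 40 of 82, 3 of 78 and 10 of 76 named called genes against MEFs in that order, and for 38 of 58, 29 of 57 and 6 of 37 in muscle against adipose, pancreas against adipose and pancreas against muscle. Folds that involve adipose moved most often, and single folds moved by over 4 times in other comparisons too.

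The steps were tested on simulated data with 200 genes changed. The Benjamini-Hochberg cut is stricter when fewer genes change, so these rates do not carry over to comparisons with many more changed genes. Of genes changed 4-fold the test recovered 32.8% for adipose against MEFs (14403 genes tested), 25.8% for muscle against MEFs (14396) and 40.3% for pancreas against MEFs (14404). Between tissues it recovered 32.4% for muscle against adipose (14456), 33.8% for pancreas against adipose (14399) and 31% for pancreas against muscle (14390). Changes of 8-fold were recovered at 57.6%, 69.2%, 75.8%, 70.4%, 73.8% and 76.5% in that order, and changes of 2-fold at 0%, 0%, 1.41%, 0%, 0% and 0%. False calls were 4 of 57, 9 of 70, 7 of 82, 7 of 79, 3 of 70 and 5 of 79. For muscle against MEFs (14369 genes) camera gave a list of 20 genes moved 2-fold an adjusted p of 3.29e-13 and called 0 of 30 random lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.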

Results

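RNA was sequenced from 8 mouse libraries in 4 groups of 2. In 3 groups the cells had been sorted for surface fibroblast activation protein (FAP), a membrane serine protease of stromal cells, from dissociated visceral adipose tissue, skeletal muscle or pancreas. The labels call the sorted pancreas cells stellate cells, the vitamin A storing mesenchymal cells of that organ. The other group held FAP-negative mouse embryonic fibroblasts (MEFs), which had been sorted, grown for 3 passages and sorted again. The design text describes duplicate experiments that were analysed separately, so the spread below is that between these 2 experiments per group. The comparisons with MEFs ask what the FAP+ cells of different tissues have in common against a FAP-negative fibroblast, and those between tissues ask how far they differ. A difference from MEFs is also a difference between cells taken from tissue and cells from culture, which this design does not separate. The libraries held 15516319 to 27759399 estimated fragments, with 15935 to 19720 genes above 0. Levels are given as normalized fragments in CPM, mean ± SD with n = 2, and genes by symbol, which the files use as identifier in lower case. Folds are ratios fitted by edgeR's quasi-likelihood test, with log2 fold changes ± SE where shown and adjusted p by Benjamini-Hochberg over 14847 genes in each of 6 comparisons.

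Fap itself, the marker of the sort, was measured at 31.2 ± 4.54 CPM in adipose, 97.9 ± 12.8 in muscle and 60.5 ± 7.23 in pancreas FAP+ cells, against 1.44 ± 1.31 in MEFs. It was 21.5-fold higher than in MEFs in adipose (log2 4.43 ± 0.62, adjusted p = 0.00104), 67.5-fold in muscle (6.08 ± 0.67, adjusted p = 0.000397) and 41.8-fold in pancreas (5.38 ± 0.65, adjusted p = 0.000601). Dpp4, the closest relative of Fap among the dipeptidyl peptidases, had 3 fragments in the 2 MEF libraries together. Its ratio to MEFs was 954 in adipose (95% counting interval 365 to 5170), 2720 in muscle (1040 to 14800) and 2060 in pancreas (790 to 11200), with adjusted p of 0.000155, 0.000118 and 0.000125. Between tissues Fap differed by log2 1.65 from adipose to muscle (adjusted p = 0.124), 0.96 from adipose to pancreas (0.297) and -0.69 from muscle to pancreas (0.713), and Dpp4 by 1.51 (0.154), 1.11 (0.24) and -0.40 (0.885). Over all genes, the 2 libraries of a group had a mean Pearson r of 0.962 on log2 CPM, higher than every other of the 105 ways to pair 8 libraries (exact one-sided p = 0.00952, the smallest possible). Libraries of FAP+ cells were closer to each other than to MEFs, by a mean r difference of 0.177 (exact one-sided p = 0.0357 over 28 splits, the smallest possible). The group pairs had r of 0.98 in MEFs, 0.918 in adipose, 0.976 in muscle and 0.973 in pancreas. Mean r between groups was 0.901 for adipose and muscle, 0.885 for adipose and pancreas, 0.926 for muscle and pancreas, and 0.712, 0.758 and 0.755 for MEFs with adipose, muscle and pancreas. These are correlations across genes, which are not independent replicates.

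In adipose FAP+ cells Clec3b, which encodes the plasminogen-binding protein tetranectin, reached 3079 ± 228 CPM and was 32100-fold higher than in MEFs (log2 14.97 ± 0.99, adjusted p = 4.78e-05). Clec3b had 6 fragments in the 2 MEF libraries together, so its fold is uncertain, and recovered reads gave log2 13.5. Complement component C3 reached 8050 ± 4600 CPM (7490-fold, 12.9 ± 0.87, adjusted p = 5.03e-05). The methyltransferase gene Inmt was 21000-fold higher (5 fragments in MEFs), Tnxb (tenascin-X) 5830-fold, Serping1 (C1 inhibitor) 1700-fold and Dpt (dermatopontin, a matrix protein) 1660-fold. MEFs held more Spp1 (osteopontin), at 5785 ± 44.5 CPM, which was 2090-fold lower in adipose cells (log2 -11.0 ± 0.99, adjusted p = 0.000148). Hmga2, a chromatin protein of embryonic cells, was 2040-fold lower, Col2a1 (cartilage collagen) 1550-fold, Col11a1 894-fold, the imprinted growth factor gene Igf2 555-fold and its neighbour H19 380-fold. Adipose held 8 fragments of Hmga2 and 7 of Col11a1 (log2 -9.8, and -8.63 in recovered reads). In all, 3994 genes were higher and 3451 lower, which is 50.1% of the genes tested. The total of 7445 calls was 4588 in a fit of only the groups compared. Without MEF library 1 it was 4321, and 81 of the 85 named genes called in this comparison were still called, against 83 without MEF library 2 and 85 without any other library. Higher genes were 53.6% of calls here but 19.3% to 24.4% with the authors' FPKM values and limma, where the median over all genes moved to log2 -0.929 when genes under 1 FPKM were left out. The FPKM fits lack TMM scaling, whose factors were 0.516 and 0.889 in adipose and 1.31 in both MEF libraries. The shift can thus include an offset between libraries.

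In muscle FAP+ cells Pi16, a peptidase inhibitor gene of fibroblasts around vessels, was higher than in MEFs, at 3599 ± 961 CPM (17800-fold, log2 14.1 ± 0.64, adjusted p = 4.44e-05). Clec3b was 23500-fold higher and Myoc (myocilin, a secreted glycoprotein) 13000-fold, at 1839 ± 106 CPM. MEFs held 6 fragments of Clec3b, 9 of Myoc and 13 of Pi16. Tnxb was 8070-fold, C3 2270-fold and Serping1 1050-fold higher. Hmga2 was 1130-fold lower (log2 -10.1 ± 0.50, adjusted p = 4.44e-05) and Il1rn, the interleukin-1 receptor antagonist, 1100-fold lower (5 fragments in muscle). Col2a1 was 323-fold, Spp1 182-fold and Igf2 106-fold lower, and Acta2, the smooth muscle actin of myofibroblasts, 78.2-fold lower. There were 3524 genes higher and 2976 lower, 43.8% of those tested. The total of 6500 calls was 3676 without muscle library 1, 3382 without muscle 2, 3842 without MEF 1 and 4271 without MEF 2, where 75, 75, 76 and 76 of the 78 named genes remained called. Higher genes were 54.2% of calls here and 27.3% to 39.6% with FPKM and limma (median over all genes down to log2 -0.59).

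In pancreas FAP+ cells Clec3b was 25500-fold higher than in MEFs (2447 ± 54.8 CPM against 6 fragments in MEFs, log2 14.6 ± 0.98, adjusted p = 6.15e-05), Pi16 9610-fold, Tnxb 5090-fold, C3 1670-fold, Dpt 1290-fold and Serping1 669-fold. Among genes lower than in MEFs, Col2a1 differed 4960-fold (log2 -12.3 ± 1.07, adjusted p = 0.000152) and Hmga2 1300-fold. Pancreas held 8 fragments of Col2a1, and recovered reads gave it log2 -10.9. Il1rl1, which encodes the interleukin-33 receptor, was 644-fold lower, Ltbp2 (a latent TGF-beta binding protein relative of microfibrils) 332-fold and Igf2 198-fold. There were 3434 genes higher and 2876 lower, 42.5% of those tested. The total of 6310 calls was 3506 without pancreas library 1, 3597 without pancreas 2, 3558 without MEF 1 and 4159 without MEF 2, where 74, 76, 74 and 75 of the 77 named genes remained called. Higher genes were 54.4% of calls here and 31.6% to 44.5% with FPKM and limma (median down to log2 -0.465).

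Gene lists fixed before the data were examined were compared with MEFs, with counts given in the order adipose, muscle and pancreas. Of 20 fibroblast-enriched genes, 20, 19 and 19 were higher and 0 lower, with the same counts adjusted over the list alone. Htra3, a secreted protease, was 1040-fold higher in adipose (6860 ± 6470 CPM) and Abca8a, a lipid transporter, 7030-fold higher in muscle (5 fragments in MEFs). Camera's adjusted p for this list was 4.63e-11, 3.48e-11 and 7.14e-11, and adjusted p = 0.147, 0.141 and 0.134 with an estimated correlation. Of 18 basement membrane genes 14, 13 and 13 were higher and 0, 1 and 1 lower (14, 14 and 13 higher, 0, 1 and 1 lower, adjusted over the list alone). Lama2, the laminin chain around muscle fibres, was 166-fold, 126-fold and 124-fold higher, and Col15a1 438-fold higher in adipose. The list's adjusted p was 1.33e-06, 7.44e-05 and 4.38e-05, and adjusted p = 0.193, 0.292 and 0.251 with an estimated correlation. Of 20 interstitial collagens and matrix glycoproteins 13, 12 and 10 were higher and 2, 3 and 3 lower (adjusted over the list alone, 13, 12 and 10 higher and 2, 3 and 4 lower). Col14a1 was 119-fold and Prelp 79.8-fold higher in adipose. Camera passed this list in adipose (adjusted p = 0.0025) and muscle (0.00865) and not in pancreas (0.0969), and gave adjusted p = 0.315, 0.428 and 0.63 with an estimated correlation. Pancreas against adipose, the test of that difference, gave 0.00637, and 0.329 with an estimated correlation. The list's median there lay at log2 0.0686 in log2(FPKM + 1), above 0 but below the median over all genes of 0.114. Of 19 metalloproteinases, lysyl oxidases and inhibitors 11, 13 and 12 were higher and 3, 4 and 4 lower (11, 13 and 12 higher and 4, 5 and 5 lower adjusted over the list alone). They included Adamts2, a procollagen protease, 74.2-fold higher in adipose, and Timp4, with 1 fragment in MEFs and a ratio of 1240 (95% counting interval 305 to 67000). Adjusted p for the list was 0.0341, 0.0607 and 0.108, and adjusted p = 0.193, 0.292 and 0.289 with an estimated correlation. Of 14 progenitor surface markers 9, 8 and 8 were higher and 2, 3 and 4 lower, with the same counts adjusted over the list alone, and camera gave 0.139, 0.228 and 0.455.

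Lists of immune signalling and of the response to tissue dissociation were compared with MEFs in the same order. Of 21 chemokines and cytokines 17 were higher in each tissue and 2, 4 and 4 lower (17 higher and 3, 4 and 4 lower adjusted over the list alone). Ccl11 (eotaxin) had 2 fragments in MEFs, and its ratio was 11200 in adipose (95% counting interval 3660 to 109000) and 7600 in muscle (2490 to 74200). Il6 was 1130-fold, 339-fold and 141-fold higher and Il33, an alarmin, 319-fold higher in muscle. Adjusted p for the list was 3.97e-06, 1.53e-05 and 0.000157, and adjusted p = 0.147, 0.141 and 0.152 with an estimated correlation. Of 14 complement genes 11, 11 and 10 were higher and 1, 2 and 1 lower (11, 11 and 11 higher, 1, 2 and 1 lower, adjusted over the list alone), among them C1s, 652-fold, and Cfb, 877-fold higher in adipose (log2 9.78, and 7.54 in recovered reads). Adjusted p was 5.78e-06, 7.68e-05 and 3.89e-05, and adjusted p = 0.193, 0.295 and 0.251 with an estimated correlation. Of 21 genes of MHC class I and interferon response 20, 20 and 19 were higher and 0 lower, with the same counts adjusted over the list alone. Irf7, a regulator of interferon genes, was 120-fold higher in adipose and 50.7-fold in pancreas, and Psmb8, an immunoproteasome subunit, 65.9-fold in adipose. Adjusted p was 1.68e-09, 5.77e-10 and 1.19e-09, and adjusted p = 0.131, 0.0573 and 0.082 with an estimated correlation. Of 22 immediate-early and dissociation genes, which rise when tissue is taken apart, 22, 21 and 20 were higher and 0 lower, also adjusted over the list alone. Fos was 90.9-fold, 200-fold and 203-fold higher, Fosb 677-fold in adipose and Hspa1a, which shares sequence with Hspa1b, 387-fold in muscle. Adjusted p was 4.63e-11, 7.3e-12 and 5.52e-10, and adjusted p = 0.131, 0.0573 and 0.0826 with an estimated correlation.

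Of 17 genes of retinoid handling and stellate cells 12, 11 and 10 were higher and 3, 2 and 2 lower (13, 11 and 10 higher, 3, 2 and 2 lower, adjusted over the list alone). Cygb, a globin of stellate cells, was 847-fold higher in adipose and 1220-fold in pancreas, and Aldh1a2, a retinoic acid synthase, 81.0-fold in pancreas. Adjusted p was 0.000867, 0.00176 and 0.00324, and adjusted p = 0.177, 0.151 and 0.152 with an estimated correlation. Of 15 adipogenic regulators and lipid uptake genes 10, 10 and 9 were higher and 1, 3 and 2 lower, with the same counts adjusted over the list alone. Lpl, the lipoprotein lipase, was 186-fold, 220-fold and 393-fold higher and Fabp4, a fatty acid carrier, 915-fold in adipose (3614 ± 4000 CPM). Adjusted p was 0.000326, 0.0176 and 0.0307, and adjusted p = 0.193, 0.296 and 0.296 with an estimated correlation. Cell cycle genes were lower for 24 of 24 members in each tissue, also adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, was 52.6-fold, 68.4-fold and 163-fold lower. Adjusted p was 4.63e-11, 8.04e-13 and 1.13e-13, and adjusted p = 0.193, 0.158 and 0.152 with an estimated correlation. Of 16 myofibroblast and contractile genes 0 were higher and 11, 14 and 14 lower, also adjusted over the list alone. Acta2 was 25.6-fold, 78.2-fold and 77.6-fold lower and Tagln (transgelin) 27.9-fold, 46.1-fold and 46.7-fold. Adjusted p was 0.000202, 2.02e-07 and 1.1e-06, and adjusted p = 0.14, 0.0573 and 0.082 with an estimated correlation. Of 16 glycolysis genes 3, 2 and 1 were higher and 6, 9 and 9 lower (3, 2 and 3 higher and 6, 10 and 10 lower adjusted over the list alone). Pfkl, a phosphofructokinase, was 9.39-fold lower in muscle and 10.6-fold in pancreas. Adjusted p was 0.0752, 0.0042 and 0.0022, and adjusted p = 0.211, 0.141 and 0.134 with an estimated correlation. Muscle and pancreas against adipose gave 0.0163 and 0.00992 for this list, and 0.252 and 0.183 with an estimated correlation. Its medians lay above 0 in log2(FPKM + 1), at log2 0.0415 and 0.236, where the medians over all genes were 0.0776 and 0.114.

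Of 16 genes of cholesterol synthesis 11, 8 and 12 were lower and 0 higher (11, 9 and 13 lower adjusted over the list alone), including Idi1, 9.76-fold lower in pancreas. Adjusted p was 0.0059, 0.0104 and 1.1e-05, and adjusted p = 0.385, 0.471 and 0.251 with an estimated correlation. Of 35 Hox genes, which encode position along the body axis, 4, 2 and 4 were higher and 13, 19 and 20 lower (4, 2 and 4 higher and 13, 21 and 21 lower adjusted over the list alone). Hoxa10 was 476-fold lower in adipose and 189-fold in pancreas, and Hoxa11 116-fold in muscle. Adipose held 6 fragments of Hoxa10 (log2 -8.89, and -7.59 in recovered reads) and muscle 6 of Hoxa11. Hoxd13, with 0 fragments in adipose, was at least 133-fold lower there against a floor of 3 fragments per library. Adjusted p was 0.0318, 1.1e-05 and 4.38e-05, and adjusted p = 0.193, 0.0573 and 0.082 with an estimated correlation. Of 29 regional transcription factors 5, 6 and 10 were higher and 13, 9 and 11 lower (6, 6 and 10 higher and 14, 9 and 11 lower adjusted over the list alone), with camera at 0.0562, 0.226 and 0.42. The same order of tissues gave 0.515, 0.752 and 0.861 for 20 TGF-beta, activin and BMP ligands and antagonists, of which 7, 7 and 4 were higher and 4, 4 and 5 lower (7, 8 and 5 higher and 4, 4 and 5 lower adjusted over the list alone). For 20 paracrine growth factors it gave 0.515, 0.752 and 0.584, with 7, 5 and 6 higher and 4 lower in each (7, 6 and 7 higher and 4, 5 and 5 lower adjusted over the list alone). For 14 haematopoietic support factors camera gave 0.253, 0.31 and 0.62, with 6, 6 and 4 higher and 3 lower in each (6, 6 and 4 higher and 3, 4 and 3 lower adjusted over the list alone). For 20 genes of the canonical Wnt pathway it gave 1, 0.287 and 0.75, with 8, 6 and 7 higher and 6, 3 and 5 lower (8, 8 and 7 higher and 7, 4 and 6 lower adjusted over the list alone).

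The fixed genes tied to loss of muscle and of blood cells, the subject of the series title, were compared in all tissues. Igf1, a muscle growth factor, was 27.9-fold, 15-fold and 10.3-fold higher than in MEFs in adipose, muscle and pancreas, and 634 ± 21.4 CPM in pancreas. Igf1 was 2.7-fold lower in pancreas than in adipose (adjusted p = 0.0368), a comparison in which nearly all named calls ended in some fit with 1 library left out. Kitl, the stem cell factor, was 3.6-fold higher in adipose (17.4 ± 10.3 against 4.85 ± 1.13 CPM, adjusted p = 0.0104), and without MEF library 1 its adjusted p was 0.0892. In muscle and pancreas Kitl differed by log2 0.26 ± 0.43 (adjusted p = 0.647) and 1.10 ± 0.43 (0.0732), and muscle against adipose gave -1.58 (0.0783). Fst, the activin antagonist follistatin, reached 166 ± 34.8 CPM in muscle, 54.3 ± 4.6 in pancreas and 84.1 ± 1.02 in MEFs. Its log2 difference from MEFs was -0.25 in adipose, 0.98 in muscle and -0.63 in pancreas (adjusted p = 0.584, 0.0631 and 0.199). Cxcl12, a chemokine of the bone marrow niche, was at 1216 ± 156 CPM in MEFs and 521 ± 166 in muscle. Its log2 differences were -0.86, -1.22 and -0.68 (adjusted p = 0.152, 0.0661 and 0.265). From adipose to muscle, adipose to pancreas and muscle to pancreas, Fst differed by log2 1.23, -0.38 and -1.61 (adjusted p = 0.0995, 0.559 and 0.0641) and Cxcl12 by -0.36, 0.18 and 0.54 (0.656, 0.84 and 0.759). Lama2 differed by -0.40, -0.42 and -0.02 (0.435, 0.411 and 0.999), and Kitl by -0.75 from adipose to pancreas (0.305) and 0.83 from muscle to pancreas (0.474). Recovered reads called 10 values of these genes that estimated fragments did not. Against MEFs these were Fst (log2 0.86) and Cxcl12 (-1.56) in muscle and Kitl (1.06) and Cxcl12 (-0.89) in pancreas. Against adipose they were Igf1 (-1.49), Kitl (-2.54) and Cxcl12 (-1.18) in muscle and Fst (-1.19) and Kitl (-1.49) in pancreas, and in pancreas against muscle Fst (-1.43). DESeq2 and the fit of only the groups compared also called Fst and Cxcl12 in muscle against MEFs and Fst in pancreas against muscle.

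Markers of other cell types were measured in the same way. Of 18 acinar genes 18 were higher in pancreas than in MEFs, also adjusted over the list alone, against 2 higher and 1 lower in adipose and 1 higher and 3 lower in muscle. Amy2a5, an amylase, was at least 526-fold and Ctrb1, a chymotrypsinogen, at least 309-fold higher in pancreas, with 0 fragments in MEFs. Adjusted p was 0.951, 0.835 and 2.54e-10 in adipose, muscle and pancreas, and adjusted p = 0.251 in pancreas with an estimated correlation. Summed acinar levels were 275 CPM in pancreas library 1 and 129 in pancreas 2, against 2.74 ± 0.28 in MEFs. Islet genes were higher for 1, 1 and 4 of 7 and lower for 1, 0 and 0 (the same adjusted over the list alone), with Ins2 at least 20.7-fold, 32.6-fold and 45.1-fold higher in adipose, muscle and pancreas and not called between pancreas and muscle (adjusted p = 0.94). Adjusted p was 0.996, 0.453 and 0.0273, and adjusted p = 0.251 in pancreas with an estimated correlation. Duct and other epithelial genes were higher for 1, 1 and 7 of 13 and lower for 5, 4 and 1 (adjusted over the list alone, 1, 1 and 7 higher and 5, 4 and 2 lower), with Krt8, a simple keratin, 80.8-fold higher in pancreas. Adjusted p was 0.372, 0.063 and 0.0956. Mesothelial genes were higher for 6, 2 and 9 of 14 and lower for 2, 4 and 1 (6, 3 and 9 higher and 2, 4 and 1 lower adjusted over the list alone), among them Rspo1, 138-fold higher in adipose and 35.8-fold in pancreas. Adjusted p was 0.168, 0.188 and 0.00223, and adjusted p = 0.319 in pancreas with an estimated correlation.

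Endothelial genes were higher for 13, 10 and 7 of 14 and lower for 0, 0 and 3 (13, 11 and 7 higher and 0, 0 and 4 lower adjusted over the list alone). Cldn5, a tight junction protein, had 2 fragments in MEFs and a ratio of 7370 in adipose (95% counting interval 2410 to 72000), and Tek, the angiopoietin receptor, was 94.8-fold, 132-fold and 88.8-fold higher. Adjusted p was 9.63e-07, 0.000588 and 0.247, and adjusted p = 0.229 and 0.428 in adipose and muscle with an estimated correlation. Summed endothelial levels were 969.5 ± 2.19 CPM in adipose, 209.6 ± 97.7 in muscle, 126 ± 3.82 in pancreas and 40.2 ± 1.18 in MEFs. Red blood cell genes were higher for 3, 3 and 0 of 4 (the same adjusted over the list alone). Their sum was 1414 CPM in adipose library 1 and 128 in adipose 2, against 90.4 ± 28.5 in muscle, 1.38 ± 0.40 in pancreas and 0.633 ± 0.12 in MEFs. Adjusted p was 0.0421, 0.0728 and 0.817, and adjusted p = 0.193 in adipose with an estimated correlation. Globin genes such as Hba-a2 share near-identical copies, so the value of each is uncertain. Myeloid genes were higher for 8, 2 and 2 of 10 and lower for 0, 1 and 1 (9, 1 and 0 higher and 0, 1 and 0 lower adjusted over the list alone). Fcer1g was 152-fold and the lysozyme gene Lyz2 21.4-fold higher in adipose. Adjusted p was 0.000708, 0.552 and 0.434, and adjusted p = 0.193 in adipose with an estimated correlation. Of mature adipocyte genes 9, 4 and 1 of 11 were higher and 0, 0 and 1 lower, also adjusted over the list alone, with Plin1, the lipid droplet perilipin, at least 58.1-fold higher in adipose. Adjusted p was 0.000284, 0.235 and 0.495, and adjusted p = 0.193 in adipose with an estimated correlation. The sums in adipose cells were 179 ± 37.4 CPM for adipocyte and 60.1 ± 29.3 for myeloid genes.

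Myofibre genes were higher for 5, 9 and 5 of 18 and lower for 1, 0 and 1 (3, 10 and 3 higher and 1, 0 and 1 lower adjusted over the list alone). Ckm, the muscle creatine kinase, was 100-fold higher in muscle, and Ttn (titin) 31.2-fold, 15.5-fold and 10.8-fold higher in adipose, muscle and pancreas and not called between muscle and adipose (adjusted p = 0.278). Adjusted p was 0.231, 0.00334 and 0.39, and adjusted p = 0.471 in muscle with an estimated correlation. Satellite cell genes were higher for 3 of 5 in each tissue and lower for 0 (the same adjusted over the list alone). The 3 called in muscle were Msc (204-fold), Chrd (11.3-fold) and Heyl (27.4-fold), none of which is restricted to satellite cells. Adjusted p was 0.0665, 0.0484 and 0.0815, and adjusted p = 0.421 in muscle with an estimated correlation, and no difference between tissues passed (0.768, 0.594 and 0.745). Schwann cell genes were higher for 1, 2 and 3 of 7 and lower for 0 (the same adjusted over the list alone), with Egr2 17.0-fold, 9.51-fold and 14.8-fold higher and Mbp, myelin basic protein, 6.38-fold higher in muscle and 4.34-fold in pancreas. Adjusted p was 0.756, 0.0385 and 0.121, and adjusted p = 0.25 in muscle with an estimated correlation. Egr2 is also an immediate-early gene. Genes of pericytes and smooth muscle were higher for 7, 4 and 6 of 12 and lower for 4, 3 and 3 (7, 5 and 6 higher and 4, 4 and 3 lower adjusted over the list alone), with adjusted p of 0.328, 0.969 and 0.86. Chondro-osteogenic and tendon genes were higher for 2, 5 and 2 of 14 and lower for 8, 6 and 8 (2, 5 and 2 higher and 9, 6 and 9 lower adjusted over the list alone), with the tendon regulator Scx 45.1-fold, 18.5-fold and 181-fold lower. Adjusted p was 0.0188, 0.45 and 0.00299, and adjusted p = 0.193 and 0.152 in adipose and pancreas with an estimated correlation. Of lymphocyte markers 2 were measured, too few to test, and Cd52 was at least 21.5-fold higher in adipose while Lck was 14-fold lower in muscle. Over all 204 list tests camera passed 99 (49 higher, 50 lower), while with an estimated correlation 46 had an unadjusted p below 0.05 and 0 passed after adjustment (lowest 0.0573). Of the 99, 8 and 18 did not pass without adipose library 1 and 2, 3 and 5 without muscle 1 and 2, 7 and 1 without pancreas 1 and 2, and 1 and 4 without MEF 1 and 2. A list's median, mean and test differed in sign in 17 tests, of which 0 passed.

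Against MEFs, 2456 genes were higher and 2006 lower in FAP+ cells of all 3 tissues. The 6 named higher genes were Clec3b, Tnxb, C3, Pi16, Dpt and Serping1, with folds from 669 (Serping1 in pancreas) upward in each tissue. The 6 named lower genes were Hmga2, Col2a1, Igf2, Il1rn, Il1rl1 and Igfbp2, an IGF binding protein, of which Igfbp2 was 254-fold lower in pancreas. The 3 comparisons use the same MEF libraries. In 20 simulations all 8 libraries, MEFs included, were drawn at the MEF mean of each gene. They gave a mean of 0.05 genes higher in all 3 and 0 lower. No gene differs in them, so counts near 0 follow by construction and give no chance level for the overlap. Lists of the same sizes drawn independently would share 219 and 134 genes. The covariance of log2 fold changes was 5.68 for adipose and muscle, 5.51 for adipose and pancreas and 5.26 for muscle and pancreas, against simulated values of 0.145, 0.144 and 0.145. The correlations were 0.869, 0.834 and 0.869, against 0.486, 0.483 and 0.49 in the simulations. The 2 MEF libraries were not split, since each part would hold only 1, so part of the excess in counts may come from the shared controls. The count of shared higher genes was 880 to 1111 and that of shared lower genes up to 3266 with FPKM and limma. The count of shared higher genes was 1461 without MEF library 1. That of shared lower genes was 976 without MEF 1, 1251 without MEF 2, 1096 and 1019 without muscle 1 and 2, and 1099 and 1069 without pancreas 1 and 2.

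**Figure D1:**
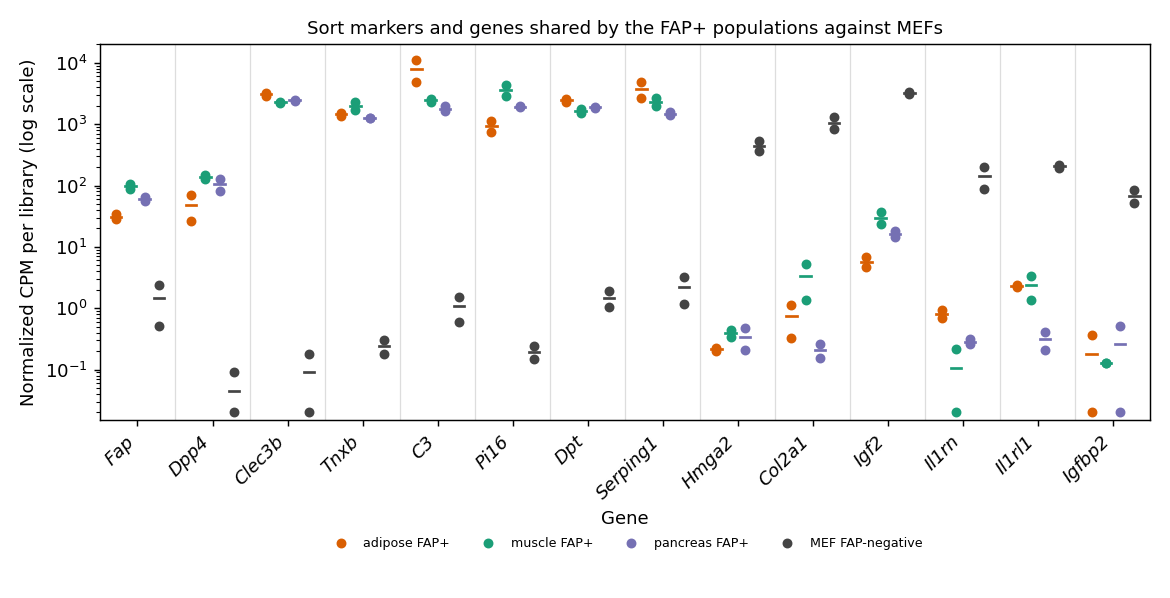
Normalized CPM on a log axis of 14 genes in the 8 libraries, with a point per library, a bar at the mean of 2, and values below 0.02 CPM drawn at 0.02. Fap, Dpp4 and the 6 shared higher genes lie above MEFs in every FAP+ library, and the 6 shared lower genes lie below MEFs, where Igf2 reached 3198 ± 200 CPM.

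Muscle and adipose FAP+ cells differed in 908 genes, 347 higher and 561 lower in muscle. Myoc was 161-fold higher in muscle, at 1839 ± 106 against 11.4 ± 1.22 CPM (log2 7.33 ± 0.35, adjusted p = 0.000497). Thbs4 and Comp, thrombospondins of tendon and cartilage matrix, were 174-fold and 123-fold higher, and the integrin gene Itgb7 and the limb transcription factor Shox2 118-fold each. In adipose cells Tcf21, a mesodermal transcription factor, reached 591 ± 361 CPM against 2 fragments in muscle, a ratio of 10200 (95% counting interval 3190 to 95100, adjusted p = 0.00128). Haptoglobin (Hp) was 258-fold lower in muscle, at 607 ± 60.4 CPM in adipose, Col6a5 88.8-fold, Fabp4 81.9-fold and Sult1e1, an estrogen sulfotransferase, 70.2-fold lower. The call count was 74 in a fit of only the groups compared, 1951 with DESeq2, 1934 in recovered reads and 414 to 508 with FPKM and limma. It was 51 without muscle library 1, 95 without muscle 2, 329 and 324 without pancreas 1 and 2, 432 and 390 without MEF 1 and 2, and 5410 without adipose 2. Of the 58 named genes called, 51 and 57 remained called without adipose 1 and 2, 16 and 19 without muscle 1 and 2, 27 and 28 without pancreas 1 and 2, and 37 and 34 without MEF 1 and 2. Higher genes were 38.2% of calls here, 29.9% with DESeq2 and 46.9% with upper quartile scaling, which moved the median over all genes to log2 0.113. They were 49.5% to 58% with FPKM and limma (median up to log2 0.326).

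Regional transcription factors were higher in muscle than in adipose for 7 of 29 and lower for 3 (9 and 4 adjusted over the list alone), camera adjusted p = 0.0466 and adjusted p = 0.358 with an estimated correlation. Tbx15 was 250-fold, the forelimb factor Tbx5 212-fold and the hindlimb factor Pitx1 79.9-fold higher. Of 35 Hox genes 3 were higher and 6 lower in muscle (5 and 11 adjusted over the list alone), with Hoxb5 8.76-fold and Hoxa5 4.1-fold lower, adjusted p = 0.0128 and adjusted p = 0.237 with an estimated correlation. The higher ones included Hoxa10, 146-fold (log2 7.19, and 5.94 in recovered reads, with 6 fragments in adipose), so the genes moved in both directions. Chondro-osteogenic and tendon genes were higher for 4 of 14 and lower for 1 (7 and 1 adjusted over the list alone), with Chad 51.8-fold and Runx2 7.06-fold higher, adjusted p = 0.00226 and adjusted p = 0.237 with an estimated correlation. Of 21 chemokines and cytokines 1 was higher and 4 lower (4 and 11 adjusted over the list alone), with Ccl2 7.46-fold and Il6 3.32-fold lower, adjusted p = 0.00393 and adjusted p = 0.297 with an estimated correlation. Complement genes were lower for 3 of 14 and higher for 0 (5 lower adjusted over the list alone), adjusted p = 0.0163 and adjusted p = 0.598 with an estimated correlation. Contractile genes were lower for 6 of 16 and higher for 0 (10 lower and 1 higher adjusted over the list alone), with Lmod1 6.44-fold lower, adjusted p = 0.000443 and adjusted p = 0.237 with an estimated correlation. Glycolysis genes were lower for 2 of 16, Hk2 (3.62-fold) and Slc2a1 (3.37-fold), and for 4 adjusted over the list alone, adjusted p = 0.0163 and adjusted p = 0.252 with an estimated correlation. Their median was log2 0.0415 in log2(FPKM + 1), above 0 but below the median over all genes of 0.0776. Basement membrane genes gave 0 higher and 0 lower calls of 18 (0 and 6 adjusted over the list alone), adjusted p = 0.00306 and adjusted p = 0.472 with an estimated correlation.

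These differences lay beside others in markers of other cell types. Endothelial genes were lower in muscle than in adipose for 4 of 14 (13 adjusted over the list alone), with Cldn5 34.1-fold lower, adjusted p = 5.24e-07 and adjusted p = 0.321 with an estimated correlation. Myeloid genes were lower for 6 of 10 (8 adjusted over the list alone), with Fcer1g 58.4-fold lower, adjusted p = 5.24e-07 and adjusted p = 0.237 with an estimated correlation. Mature adipocyte genes were lower for 2 of 11 (9 adjusted over the list alone), where Cidec was at least 12.9-fold lower, adjusted p = 1.04e-06 and adjusted p = 0.237 with an estimated correlation. Mesothelial genes were lower for 4 of 14 (7 adjusted over the list alone), with Rspo1 56.6-fold lower, adjusted p = 1.33e-05 and adjusted p = 0.297 with an estimated correlation. Wt1, which belongs to the mesothelial list and is also expressed in visceral stroma, had 3 fragments in muscle and a ratio of 955 in adipose over muscle (95% counting interval 349 to 4950). Pericyte and smooth muscle genes were lower for 6 of 12 and higher for 1 (8 and 1 adjusted over the list alone), with Myh11 5.61-fold lower (not called in recovered reads, log2 -1.70), adjusted p = 0.000443 and adjusted p = 0.321 with an estimated correlation. Myofibre genes were higher in muscle for 4 of 18 and lower for 1 (7 and 1 adjusted over the list alone), with Ckm 53.3-fold higher, adjusted p = 0.00764 and adjusted p = 0.598 with an estimated correlation. Schwann cell genes were higher for 2 of 7, also adjusted over the list alone, one of them Mbp, 4.27-fold, adjusted p = 0.0466 and adjusted p = 0.297 with an estimated correlation.

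Pancreas and adipose FAP+ cells differed in 1344 genes, 493 higher and 851 lower in pancreas. Spp1 was 326-fold higher in pancreas, at 901 ± 648 against 2.78 ± 0.49 CPM (log2 8.35 ± 0.89, adjusted p = 0.00381). The gut and spleen mesoderm factor Nkx2-3 was 856-fold higher (153 ± 1.56 CPM, adjusted p = 0.00332) and Barx1, a factor of stomach mesenchyme, had 2 fragments in adipose and a ratio of 924 (95% counting interval 277 to 8270). Xist, the RNA of the inactive X chromosome, was 1300-fold higher (180.0 ± 51.5 against 0.137 ± 0.022 CPM, adjusted p = 0.0225). Xist overlaps its antisense gene Tsix, and the sources used here state no strand. Fabp4 was 1510-fold lower in pancreas, Hp 388-fold and Cldn5 335-fold, and Sult1e1, with 1 fragment in pancreas, had a ratio of 15700 in adipose over pancreas (95% counting interval 3420 to 752000). The haemoglobin genes Hba-a2 and Beta-s were 1150-fold and 2480-fold lower, with 692 ± 826 CPM of Hba-a2 in adipose. The call count was 305 in a fit of only the groups compared, 2304 with DESeq2, 3234 in recovered reads and as low as 853 with FPKM and limma. It was 32 without pancreas library 1, 8 without pancreas 2, 656 and 640 without muscle 1 and 2, 783 and 795 without MEF 1 and 2, and 5077 without adipose 2. Of the 61 named genes called, 4 and 1 remained called without pancreas 1 and 2, 42 and 42 without muscle 1 and 2, 48 and 46 without MEF 1 and 2, 57 without adipose 1 and 61 without adipose 2. Higher genes were 36.7% of calls here, 47.1% with upper quartile scaling (which moved the median over all genes to log2 0.139) and 59.3% to 63.5% with FPKM and limma (median up to log2 0.453).

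Of 21 chemokines and cytokines 10 were lower in pancreas than in adipose and 0 higher (13 and 3 adjusted over the list alone), adjusted p = 5.2e-07 and adjusted p = 0.183 with an estimated correlation. Ccl7 was 32.7-fold, Ccl2 27.3-fold and Il6 7.99-fold lower. Complement genes were lower for 3 of 14 and higher for 1 (5 and 1 adjusted over the list alone), with Cfb 4.34-fold lower, adjusted p = 0.00265 and adjusted p = 0.329 with an estimated correlation. Cholesterol synthesis gave 1 lower gene of 16, Pmvk, 5.5-fold (also 1 adjusted over the list alone), adjusted p = 0.00257 and adjusted p = 0.329 with an estimated correlation. Cell cycle gave 1 lower gene of 24, Pcna, 2.33-fold (also 1 adjusted over the list alone), adjusted p = 0.00769 and adjusted p = 0.406 with an estimated correlation. For 6 further lists camera's direction was lower while the median in log2(FPKM + 1) lay above 0. Camera sets a list against the other genes, and the FPKM median over all genes was itself at log2 0.114. The medians of adipogenic and glycolysis genes lay above it and those of the other lists below it. Among the 6 lists, adipogenic genes were lower for 5 of 15 and higher for 1 (6 and 1 adjusted over the list alone), with Cd36 297-fold lower, adjusted p = 0.0441, adjusted p = 0.329 with an estimated correlation and an FPKM median of log2 0.34. Glycolysis genes were lower for 4 of 16, also adjusted over the list alone, with Hk2 10.9-fold lower, adjusted p = 0.00992, adjusted p = 0.183 with an estimated correlation and an FPKM median of 0.236. Basement membrane genes were lower for 3 of 18 (4 adjusted over the list alone), with Lama5 10.7-fold lower, adjusted p = 0.00994, adjusted p = 0.335 with an estimated correlation and an FPKM median of 0.0817. Interstitial matrix genes were lower for 2 of 20 (3 adjusted over the list alone), with Postn (periostin) 5.32-fold lower, adjusted p = 0.00637, adjusted p = 0.329 with an estimated correlation and an FPKM median of 0.0686. Contractile genes were lower for 3 of 16 (4 lower and 1 higher adjusted over the list alone), with Acta2 3.04-fold lower, adjusted p = 0.0401, adjusted p = 0.208 with an estimated correlation and an FPKM median of 0.0706. Metalloproteinases and their inhibitors were lower for 2 of 19 (4 lower and 1 higher adjusted over the list alone), with Timp1 11-fold lower, adjusted p = 0.0197, adjusted p = 0.208 with an estimated correlation and an FPKM median of 0.0531.

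Acinar genes were higher in pancreas than in adipose for 16 of 18 (17 adjusted over the list alone), adjusted p = 6.37e-20 and adjusted p = 0.183 with an estimated correlation. Amy2a5 was at least 272-fold and Ctrb1 186-fold higher. Amylase, trypsinogen and elastase genes have near-identical copies, so the value of each is uncertain. Duct and epithelial genes were higher for 8 of 13 (11 adjusted over the list alone), with Krt18 29.5-fold and E-cadherin (Cdh1) 41.4-fold higher, adjusted p = 1.23e-07 and adjusted p = 0.208 with an estimated correlation. Summed duct levels (with Spp1) were 1672 and 553 CPM in pancreas libraries 1 and 2. Of 7 islet genes 1 was higher, Pcsk2, 7.93-fold (4 adjusted over the list alone), adjusted p = 0.00109, or 0.183 with an estimated correlation. Against MEFs Pcsk2 was lower in adipose and not called in pancreas. Endothelial genes were lower for 11 of 14 (12 adjusted over the list alone), with Cdh5, VE-cadherin, 358-fold and Pecam1 73.0-fold lower, adjusted p = 3.08e-10 and adjusted p = 0.208 with an estimated correlation. Mature adipocyte genes were lower for 6 of 11 (9 adjusted over the list alone), with adiponectin (Adipoq) at 47.1-fold (95% counting interval 14.5 to 433), adjusted p = 2.7e-08 and adjusted p = 0.183 with an estimated correlation. Myeloid genes were lower for 6 of 10 (9 adjusted over the list alone), with Lyz2 7.54-fold lower, adjusted p = 2.82e-07 and adjusted p = 0.183 with an estimated correlation. Red blood cell genes were lower for 2 of 4 (3 adjusted over the list alone), adjusted p = 0.00265 and adjusted p = 0.183 with an estimated correlation. Pericyte and smooth muscle genes were lower for 5 of 12 and higher for 1 (7 and 1 adjusted over the list alone), with Rgs5 27.2-fold lower, adjusted p = 0.00994 and adjusted p = 0.329 with an estimated correlation. Immediate-early genes, which did not pass camera's test here (adjusted p = 0.0739), were lower for 6 of 22 and higher for 1 (9 and 4 adjusted over the list alone).

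Pancreas and muscle FAP+ cells differed in 545 genes, 228 higher and 317 lower in pancreas. Nkx2-3 had 2 fragments in muscle and a ratio of 2720 (95% counting interval 825 to 24600, adjusted p = 0.00307), and Tcf21, also with 2 fragments in muscle, a ratio of 2080 (651 to 19400, adjusted p = 0.00188). Keratins of simple epithelia were higher in pancreas, Krt8 458-fold (73.5 ± 53.3 CPM) and Krt18 384-fold. Xist was 671-fold higher (log2 9.39 ± 1.89, adjusted p = 0.0411). Muscle held more Myoc (183-fold lower in pancreas, log2 -7.51 ± 0.36, adjusted p = 0.000599), the interleukin-1 decoy receptor Il1r2 (180-fold), lubricin, encoded by Prg4 (77.6-fold, log2 -6.28, and -8.38 in recovered reads), Comp (69.1-fold), Angptl1 (61.1-fold) and Thbs4 (59.6-fold). The call count was 1752 in a fit of only the groups compared, 1005 with DESeq2 and 868 in recovered reads. It was 88 and 81 without muscle library 1 and 2, 58 and 84 without pancreas 1 and 2, 272 and 286 without MEF 1 and 2, and 1205 without adipose 1 and also without adipose 2. Of the 38 named genes called, 12 and 11 remained called without muscle 1 and 2, 10 and 17 without pancreas 1 and 2, 31 without either MEF library and 38 without either adipose library. Higher genes were 41.8% of calls here and 50.8% to 53.8% with FPKM and limma (median up to log2 0.113).

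Chemokines and cytokines were lower in pancreas than in muscle for 7 of 21 and higher for 0 (11 lower adjusted over the list alone), adjusted p = 7.34e-06 and adjusted p = 0.168 with an estimated correlation. Cxcl13, a B cell attractant, was 10.1-fold, Cxcl14 5.23-fold and Cxcl10 3.88-fold lower. Chondro-osteogenic and tendon genes were lower for 4 of 14 (9 adjusted over the list alone), with Chad 106-fold lower, adjusted p = 1.33e-09 and adjusted p = 0.155 with an estimated correlation. Tnmd (tenomodulin) had 1 fragment in pancreas and a ratio of 725 in muscle over pancreas (95% counting interval 158 to 34700). Interstitial matrix genes were lower for 2 of 20, Fmod (9.42-fold) and Col12a1 (4.87-fold), and for 2 with 1 higher adjusted over the list alone, adjusted p = 0.0341 and adjusted p = 0.566 with an estimated correlation. Immediate-early genes were lower for 3 of 22 (5 adjusted over the list alone), with Hspa1b 19.9-fold and Hspa1a 16.3-fold lower, adjusted p = 0.0213 and adjusted p = 0.377 with an estimated correlation. Cholesterol synthesis had 0 of 16 called over all genes by edgeR and 9 lower adjusted over the list alone, adjusted p = 7.49e-07 and adjusted p = 0.303 with an estimated correlation. Acinar genes were higher for 17 of 18 (18 adjusted over the list alone), with Amy2a5 at least 297-fold higher, adjusted p = 2.7e-34 and adjusted p = 0.168 with an estimated correlation. Duct genes were higher for 5 of 13 (12 adjusted over the list alone), with Cdh1 39.2-fold higher, adjusted p = 9.1e-13 and adjusted p = 0.168 with an estimated correlation. Mesothelial genes were higher for 8 of 14 (11 adjusted over the list alone), with Nkain4 15.5-fold and Rspo1 14.6-fold higher, adjusted p = 6.73e-15 and adjusted p = 0.168 with an estimated correlation. Islet genes had 0 of 7 called over all genes and 3 higher adjusted over the list alone, adjusted p = 0.0169 and adjusted p = 0.303 with an estimated correlation. Endothelial genes were lower for 3 of 14 and higher for 1 (10 and 1 adjusted over the list alone), with Cdh5 34.5-fold lower, adjusted p = 2.53e-06 and adjusted p = 0.377 with an estimated correlation. Myofibre genes were lower for 3 of 18 and higher for 1 (6 and 1 adjusted over the list alone), with Myl1 45.8-fold and Tnnc2 14.1-fold lower, adjusted p = 7.34e-06 and adjusted p = 0.382 with an estimated correlation. Red blood cell genes had 0 of 4 called over all genes and 2 lower adjusted over the list alone, adjusted p = 0.00275 and adjusted p = 0.168 with an estimated correlation.

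Genes distinct to a tissue were those higher there than in both other FAP+ populations, 338 in adipose, 114 in muscle and 107 in pancreas. The 6 named for adipose were Hp, Fabp4, Col6a5, Sult1e1, angiotensinogen (Agt) and Cldn5. Those for muscle were Myoc, Thbs4, Comp, Itgb7, Prg4 and Tbx5, and those for pancreas Xist, Nkx2-3, Amy2a5, Barx1, Spp1 and Ctrb1. Several stand on lists of other cell types: Amy2a5 and Ctrb1 acinar, Spp1 duct, Cldn5 endothelial and Comp tendon. The pancreas genes include 11 acinar genes outside the trypsinogen, elastase and amylase families, besides members of these. Distinct genes may thus reflect other cells in the sort. In 20 simulations with no gene changed between groups the mean counts were 0, 0 and 0.05, which follows by construction and gives no chance level for overlap. Independent lists of the same sizes would share 32.2, 7.41 and 7.57 genes. The counts were 18, 34 and 56 with fits of only the groups compared, 861, 174 and 178 with DESeq2 and 803, 179 and 202 in recovered reads, and with FPKM and limma as low as 99 for adipose and as high as 190 for pancreas. The adipose count was 2 without pancreas library 2, 10 without pancreas 1, 11 and 33 without muscle 1 and 2, 159 and 132 without MEF 1 and 2, and 2145 without adipose 2. The muscle count was 15 and 21 without pancreas 1 and 2, 21 and 24 without muscle 1 and 2, 67 and 65 without MEF 1 and 2, and 248 without adipose 2. The pancreas count was 5 and 4 without pancreas 1 and 2, 7 and 10 without muscle 1 and 2, 61 and 63 without MEF 1 and 2, and 186 and 199 without adipose 1 and 2. Beside the pancreas genes stand the sex-linked transcripts, chosen after their values were seen. Xist was at 144 and 216 CPM in the pancreas libraries, 0.122 to 0.383 in the other FAP+ libraries, 12.8 in MEF library 1 and 0.0911 in MEF 2. The Y-linked Ddx3y and Eif2s3y were at 0 in both pancreas libraries, and at 14.7 to 47.1 CPM in all other libraries. Beside the adipose genes stands the gap between the 2 adipose libraries, in which Fabp4 was 3614 ± 4000 CPM and the actin-binding protein Gsn took 17.8% and 14.7% of fragments.

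**Figure D2:**
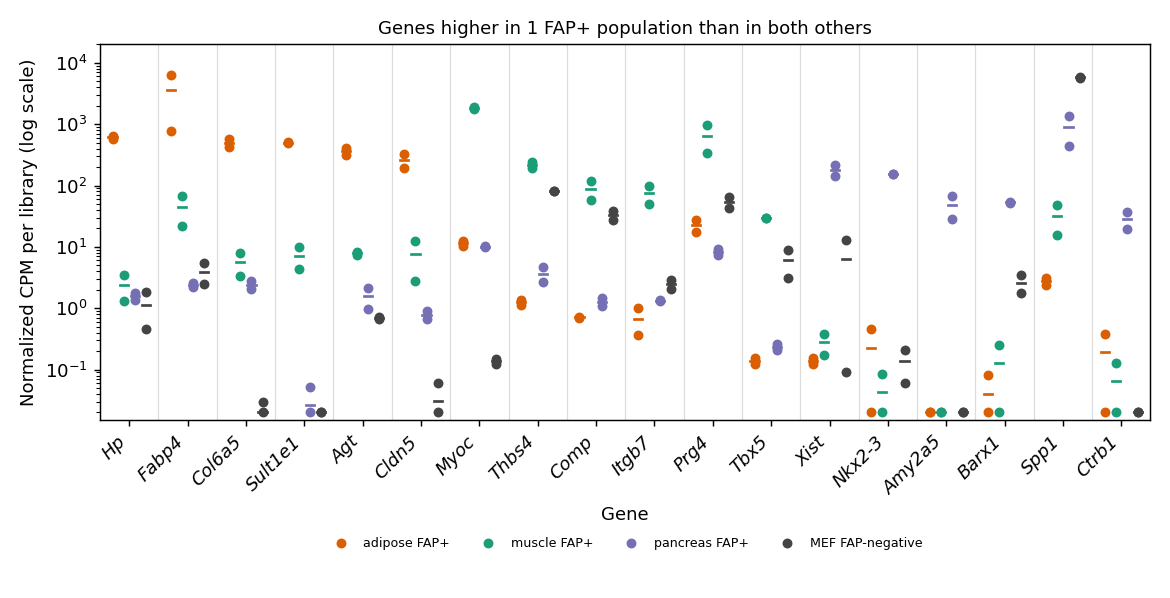
Normalized CPM on a log axis of 18 tissue-distinct genes in the 8 libraries, with a point per library, a bar at the mean of 2, and values below 0.02 CPM drawn at 0.02. Each gene is highest among FAP+ cells in its own tissue, and Spp1, highest in MEFs, differs within the pancreas pair (901 ± 648 CPM).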

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

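The sets of genes in this part followed a rule set before the data were examined, while the example genes and the counts with libraries left out or in recovered reads were chosen after the result was seen. They are genes that edgeR's quasi-likelihood test called in opposite directions against MEFs in 2 tissues, each also called between those tissues. The last condition removed no gene. Opposite calls in the same fit make it all but certain, so it adds no separate support. Adipose and muscle parted in this way over 44 genes, 20 higher in adipose and 24 higher in muscle. Tcf21 was at 591 ± 361 CPM in adipose, 0.785 ± 0.13 in MEFs and 0.0638 ± 0.09 in muscle (adjusted p against MEFs 8.85e-05 and 0.0167). Wt1 was at 78.5 ± 20, 0.346 ± 0.19 and 0.0748 ± 0.016 CPM in the same order (4.17e-05 and 0.0403), where the muscle level rested on 3 fragments (95% counting interval of the ratio 1.54 to 21.8) and the call against MEFs was lost in recovered reads (log2 -0.93). Pparg, the adipogenic receptor, was at 40.1 ± 4.41, 17.6 ± 3.95 and 4.36 ± 1.48 (0.0145 and 0.00209). The limb factor Tbx5 went the other way, at 29.4 ± 0.25 CPM in muscle, 6.01 ± 4.04 in MEFs and 0.137 ± 0.022 in adipose, as did Shox2, at 52.0 ± 7.08, 7.06 ± 4.56 and 0.449 ± 0.12. All calls were also made in recovered reads for 33 of the 44 genes. The count was 261 without adipose library 2, 10 and 14 without muscle 1 and 2, and 13 and 10 without MEF 1 and 2.

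Adipose and pancreas parted over 55 genes, 39 higher in adipose and 16 in pancreas, and muscle and pancreas over 43, of which 29 were higher in muscle and 14 in pancreas. The transcription factors Barx1, Hand2 and Isl1 were higher in pancreas than in MEFs and lower in the other tissues. Barx1 was at 53.1 ± 2.50 CPM in pancreas, 2.62 ± 1.17 in MEFs, 0.0406 ± 0.057 in adipose and 0.128 ± 0.18 in muscle. Hand2 was at 22.8 ± 4.17 CPM in pancreas, 4.98 ± 1.02 in MEFs, 0.117 ± 0.05 in adipose and 0.0429 ± 0.061 in muscle, and Isl1 at 11.3 ± 2.81, 0.801 ± 0.24, 0.0203 ± 0.029 and 0.0319 ± 0.045. All calls were also made in recovered reads for 47 of the 55 and 40 of the 43 genes. The count of 55 was 7 and 2 without pancreas library 1 and 2, 16 and 17 without MEF 1 and 2, and 114 and 242 without adipose 1 and 2. The count of 43 was 19 and 18 without muscle library 1 and 2, 17 and 21 without pancreas 1 and 2, 17 and 18 without MEF 1 and 2, and 75 and 72 without adipose 1 and 2.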

How the results depend on the processing

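The alternatives that use recovered reads and the list medians under other scalings were chosen after seeing the data, and all others before. RLE and upper quartile scaling, no filter and the stricter filter kept all 11 counts of genes within 1.5 times. DESeq2 called 1951 genes between muscle and adipose, 2304 between pancreas and adipose and 1005 between pancreas and muscle, and 861, 174 and 178 genes distinct to adipose, muscle and pancreas. Its median over all genes lay at log2 0.381, 0.461 and 0.377 against MEFs. With only the groups compared in the fit, 4588 genes were called for adipose against MEFs, 74 for muscle against adipose, 305 for pancreas against adipose and 1752 for pancreas against muscle, and 18, 34 and 56 were distinct. Such a fit holds fewer samples and takes its spread from those groups alone. The main fit shares 1 dispersion per gene over all groups, though the pair's r was 0.918 in adipose and 0.973 to 0.98 elsewhere. Fewer samples alone would not explain the rise from 545 to 1752 for pancreas against muscle. A test against a 2-fold change, stricter by construction, called 4227, 3611 and 3503 genes against MEFs in adipose, muscle and pancreas, 276, 466 and 215 between tissues in the order above, 1496 higher and 861 lower in all 3 tissues, and 82, 59 and 41 distinct. With log2(FPKM + 1) limma called 508 genes for muscle against adipose, 880 higher and 3243 lower in all 3 tissues, and 155 and 190 distinct to adipose and pancreas. With log2(FPKM + 0.1) it called 414 for muscle and 853 for pancreas against adipose, 1111 higher in all 3 and 99 distinct to adipose. At 1 FPKM or more the numbers were 495 and 872 between those tissues, 944 higher and 3266 lower in all 3, and 163 distinct to adipose. Recovered reads gave 1934, 3234 and 868 genes between tissues and 803, 179 and 202 distinct, and without adipose library 1 they gave 9846 and 9665 against MEFs in muscle and pancreas, 2161, 3248 and 1595 between tissues, 3024 lower in all 3, and 884, 258 and 325 distinct. By construction the FPKM fits lack edgeR's TMM scaling, which can shift their medians over all genes and shares of higher genes. Beyond what construction shows, the cause was not tested for these settings. With 1 library left out its group keeps a lone sample, which is assumed to vary like the other groups. Calls then ranged over 4321 to 9491, 3382 to 8987 and 3506 to 8830 against MEFs in adipose, muscle and pancreas, 51 to 5410, 8 to 5077 and 58 to 1205 between tissues, 1461 to 2950 higher and 976 to 2701 lower in all 3, and 2 to 2145, 15 to 248 and 4 to 199 distinct. Both similarity tests were rerun only with Spearman correlation, on the most variable genes, on log2(FPKM + 1) and on recovered reads. Each rerun gave the smallest possible p. The mean r within groups ranged from 0.911 on the most variable genes to 0.974 in recovered reads. The r difference of the split into FAP+ and MEF libraries ranged from 0.159 with log2(FPKM + 1) to 0.735 on the most variable genes. Of the 426 values of named genes, 55 lost and 1 gained a call with log2(FPKM + 1), 7 and 9 with DESeq2, 75 and 9 with only the groups compared, 6 and 10 with recovered reads, and 0 with RLE. The sign changed in 15 cases, none of them called in the main analysis by edgeR. With log2(FPKM + 1) these were Kitl in muscle against MEFs (log2 -0.21), Lama2 (0.094) and Cxcl12 (0.22) in muscle against adipose, Fst (0.34) and Lama2 (0.22) in pancreas against adipose and Lama2 in pancreas against muscle (0.13). Recovered reads turned Fst in adipose against MEFs (0.62) and Cxcl12 in pancreas against adipose (-0.52). Fst in adipose against MEFs was at 0.18 without adipose 1 and -0.89 without adipose 2, Cxcl12 in muscle against adipose at -0.87 and 0.41, and in pancreas against adipose Fst was at -0.82 and 0.25, Kitl at -1.26 and 0.049 and Cxcl12 at -0.32 and 0.95. Lama2 in pancreas against muscle was at 0.13 without muscle 2, 0.11 without pancreas 1 and -0.17 without pancreas 2. Levels near the floor of 0.108 to 0.193 CPM, a cut of 3 fragments chosen here, rest on few fragments. Of simulated 2-fold changes the test recovered at most 1.41%, and whether depth, the 2 libraries per group or their spread set this was not tested.

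Replicate numbers recur across groups, but no label ties them to a day. Deviations of same-numbered libraries correlated at -0.156 to 0.347 over the 6 group pairs, so a common day stays open. With the number as a block, 7202, 6428 and 6214 genes were called against MEFs in adipose, muscle and pancreas, 732, 1147 and 471 between tissues, 2416 higher and 1939 lower in all 3, and 275, 99 and 98 distinct, all within 1.5 times. Of the named values 8 lost and 1 gained a call with the block, and of 99 list calls 4 did not pass.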

Other observations

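The genes of the next 2 paragraphs were chosen after their values were seen, and of the tests in the last 3 paragraphs all but that without the 100 most abundant genes were chosen after the result was seen.

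Receptors and surface proteins of mesenchymal progenitors differed from MEFs in both directions, and their list did not pass in any tissue. Pdgfra, the receptor that marks tissue fibroblasts, was at 473 ± 178 CPM in adipose, 601 ± 120 in muscle and 502 ± 108 in pancreas against 66.5 ± 22.6 in MEFs (edgeR adjusted p = 0.00144, 0.00102 and 0.00147). Cd34 was at 1317 ± 831, 1942 ± 252 and 1791 ± 79.9 CPM against 108 ± 5.09, and Cd248, the endosialin gene, at 926 ± 523, 617 ± 250 and 720 ± 107 against 40.3 ± 1.02. The imprinted Dlk1, a surface protein of immature cells, was at 1004 ± 84.0 CPM in MEFs, 6.18 ± 0.65 in adipose, 41.4 ± 28.8 in muscle and 141 ± 16.5 in pancreas.

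Single genes of BMP and Wnt signalling differed from MEFs, although neither fixed list of these pathways passed (camera adjusted p = 0.515, 0.752 and 0.861 for the list with BMP ligands and 1, 0.287 and 0.75 for Wnt in adipose, muscle and pancreas). Gdf10, a BMP relative, was at 807 ± 151 CPM in adipose, 100.55 ± 42.4 in muscle and 165 ± 3.88 in pancreas against 1.37 ± 0.56 in MEFs (adjusted p = 4.18e-05, 0.000119 and 8.63e-05), and Sfrp4, a Wnt antagonist, at 179 ± 28.7, 145 ± 51.5 and 86.7 ± 10.2 against 1.11 ± 0.80 (0.000118, 0.000161 and 0.000226). Grem1, a BMP antagonist, was at 23.4 ± 25.4 CPM in MEFs and 0.447 ± 0.23, 0.160 ± 0.044 and 0.468 ± 0.15 in the 3 tissues (0.00301, 0.00199 and 0.00359), and its SD in MEFs exceeded the mean. Muscle cells held more Wnt2 (39.6 ± 22.7 against 2.59 ± 0.22 CPM in adipose, adjusted p = 0.00724) and more of the leptin receptor Lepr (11.98 ± 1.28 against 1.90 ± 0.11, adjusted p = 0.00852).

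Adipose library 1 stood apart from adipose library 2. The pair's r of 0.918 was below the lowest r of the other pairs by -0.0552. The gap was -0.0408 in recovered reads, -0.0456 with the trend on gene length taken out of each pair and -0.0572 without the 100 most abundant genes, so none of the bias adjustment, gene length or a few abundant genes accounts for all of it. The 2970 shortest genes were higher in adipose 1 by a median log2 of 0.83, so a length trend may account for part. A difference between the 2 animals or sorts stays open, and no biological explanation was tested.

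Acinar transcripts in the pancreas libraries may come from RNA of acinar cells carried over in the sort for FAP, a candidate explanation from a marker list fixed before the test. The median log2 ratio of 18 acinar genes between pancreas library 1 and 2 was 1.01 (SD 0.226, higher in library 1 for 18 of 18), outside the central 95% of 10000 random lists matched on level (-0.279 to 0.181), as a common source needs. Sequence shared between paralogs is argued against, since 11 acinar genes outside the trypsinogen, elastase and amylase families were higher in pancreas than in both other FAP+ populations. Amy2a5 and Ctrb1, the most abundant of all 18, reached 47.6 ± 26.9 and 28.01 ± 12.4 CPM. Low expression in the sorted cells themselves that differs between the 2 experiments stays open and was not tested.

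Pancreas libraries held Xist at 144 and 216 CPM and no Ddx3y, Eif2s3y, Kdm5d or Uty, while the adipose and muscle libraries held those Y-linked transcripts and 0.383 CPM of Xist or less, so the pancreas cells may have come from female mice and the adipose and muscle cells from males. Of the genes distinct to pancreas 3.88% lay on X or Y, Hs6st2, Sms, Tsix and Xist, against 3.33% of the genes tested (Fisher's exact p = 0.778). Sex also changes genes on other chromosomes, so sex and tissue cannot be told apart for the pancreas libraries. MEF library 1, with 12.8 CPM of Xist and 20 of Ddx3y, may hold cells of both sexes, which was not tested.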
